A study of Homo sapiens with 10 samples.

How the data were processed

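Enhanced crosslinking and immunoprecipitation (eCLIP) maps where a protein sits on RNA. Tissue is crosslinked with ultraviolet light, the RNA is fragmented, complexes are precipitated with an antibody, and the recovered RNA is sequenced beside a size-matched input taken before the precipitation step. Here the protein was TDP-43, an RNA-binding protein that forms inclusions in amyotrophic lateral sclerosis. The tissue was human frontal cortex from 2 control donors and 3 donors with sporadic amyotrophic lateral sclerosis (sALS). The series held 10 samples, of which the 5 precipitated libraries had a peak list used here and the 5 inputs had none. Libraries are named by group and replicate number, where the number is only a name.

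The authors deposited 1 peak list per library, with replicates not pooled. Each line held a position, a strand, a −log10 p-value and a log2 fold. The deposited −log10 p-values ran from 0 to 400, and the deposited log2 fold compared the precipitated library with its size-matched input, as read from the values and the series' design text. Both are the authors' own values per peak. Per the submitters' processing notes the build was hg19 and the tools were cutadapt, STAR, GATK, Picard and SAMtools, with no roles or versions. The peak caller and the scaling of the fold were not given in the sources used here. For both controls the name of the list carried the number of the other control donor; the record that ties lists to samples was followed, and the group is unaffected. The labels gave both controls the same pair of in-line barcodes and all sALS libraries another pair, so barcode set and group cannot be told apart.

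The annotation at hand was of build GRCh38. The last peak on chromosome 1 ended at 249212081, past the last annotated base of that chromosome in GRCh38, 248937043. Positions were not converted, so results are by hg19 position, 1-based, without gene names. The planned gene-level comparison, gene lists with their cell type markers, genomic features and GU repeat search were therefore not run, and CSNK1E and TARDBP were not analysed here. Chromosome Y and a 100 kb stretch of chromosome X were left out of every count, because levels there could describe a donor.

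A significant peak had a −log10 p of at least 3 and a log2 fold of at least 3, which is 8-fold. Regions were made by merging peaks of the 5 lists that overlapped by at least 1 bp on the same strand. In regions called in all 5 libraries the value was the width-weighted mean log2 fold of a library's peaks. It was compared, sALS minus control, with limma 3.58.1 in R 4.3.3, with trend and robust empirical Bayes and Benjamini-Hochberg adjustment at 0.05. A fold set within each list need not share a scale across lists, so a fit centred on library medians was also made. Significant peaks were counted in stranded 100 kb windows holding at least 5 over the libraries, as log2 of peaks plus 0.5 per 1000 significant peaks, and compared with limma with trend. Group means were compared by two-sided exact permutation over the 10 splits of the 5 libraries, whose smallest possible p is 0.1. Leaving out 1 control leaves a lone control, which limma assumes to vary like the other libraries. The tables were made in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6. All 6 set checks matched: those on made-up peak lists gave the known answers. Those on the significant peaks of the controls gave the same overlap counts as bedtools 2.31.1.

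Named regions follow a rule: the 10 with the highest mean log2 fold among those significant in all 5 libraries and, as fewer than 10 passed the test, the 10 with the smallest p in each direction, which are said not to pass. Windows follow the same rule, with mean density for mean fold. Groups, the comparisons named in this section and this rule were set before the data were examined; settings, comparisons and simulations chosen later are named as such where their values are given.

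The read depth is unknown, so no counts per peak are given. The log2 folds lay on ratios of small whole numbers plus 1 constant per library: between 95.4% and 97.3% of values whose ratio was below 20 matched such a ratio, with a denominator up to 5 and a tolerance of 0.0001, against at most 0.032% when the constant was moved by 0.1. If those whole numbers are reads, the ratio of the precipitated to the input library was 2.88 in control 1, 2.74 in control 2, 0.817 in sALS 1, 6.17 in sALS 2 and 2.67 in sALS 3. An 8-fold peak over 1 input read would then need 24, 22, 7, 50 and 22 reads. This is an inference from the values, since no label states the scaling; under it the significance threshold would not mean the same number of reads in each library.

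Both limma fits were tested on simulated data with 20 draws per setting. With the raw residual SD of each region as the simulated spread, a log2 change of 3 was recovered in 0% of 200 regions among 10147, and a change of 4 in 0.85%. This was the spread tried first. After its result was seen, limma's moderated SD was added as a second spread, which recovered 44.2% at a change of 3 and 83.9% at 4. For 106 of 530 windows the raw SD gave 4.15% at 3 and 43.1% at 4, and the moderated SD 17.2% and 59.2%. At a log2 change of 2 the recovered share was at most 4.48% on average in these simulations, so a count of 0 calls leaves changes of that size open. With the raw SD it also leaves open changes of 3 in regions and windows, and of 4 in regions. Under no setting were all changed regions or windows recovered, so 0 calls does not exclude single changes of 3 or 4. Numbers of changed features other than 200 regions and 106 windows were not simulated.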

Results

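TDP-43 binding was mapped by eCLIP in post-mortem frontal cortex of 2 control donors and 3 sALS donors, each with a size-matched input. The design asks whether the RNA sites held by TDP-43 differ in sALS. The lists held 107567 called peaks in control 1, 69180 in control 2, 44781 in sALS 1, 112331 in sALS 2 and 59241 in sALS 3. Median peak width lay between 38 and 43 bp. Merging the lists gave 194897 stranded regions, of which 10147 held a peak in all 5 libraries and 114133 in 1 library. All positions are hg19, 1-based, and an annotation of that build was not used here. The values of fold and p are the authors', relative to the input of the same donor.

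Every library had a significant peak, at least 8-fold over input, at 78 regions, against 0.0928 if significance were independent between libraries within regions called in all 5. That figure takes each region as equally likely to pass, so the excess over it does not measure how well sites repeat. The 78 regions had a median width of 196.5 bp, against library medians of 72 to 78 bp for significant peaks. Significant peaks of different libraries in 1 region therefore need not overlap each other. The highest mean enrichment lay on chromosome 11 at 131550254 to 131550399 on the plus strand, with a log2 fold of 5.05 ± 0.77 (SD, n = 5). A second region 3' of it, at 131550578 to 131550631, had 4.93 ± 0.69 (SD, n = 5). Chromosome 19 held 3 of the leading regions. The region at 11576002 to 11576166 on the minus strand had 4.90 ± 1.20, that at 7907257 to 7907422 on the plus strand 4.62 ± 0.77, and that at 57021951 to 57022099 on the plus strand 4.56 ± 0.91 (SD, n = 5 each). The region on chromosome 1 at 109642876 to 109642954 on the plus strand had 4.89 ± 0.99 (SD, n = 5). Chromosome 10 had 4.68 ± 0.60 at 135022485 to 135022738 on the plus strand, and chromosome 4 had 4.60 ± 0.84 at 880731 to 880902 on the minus strand (SD, n = 5 each). Chromosome 16 had 4.55 ± 0.80 at 6823194 to 6823320 on the plus strand, and chromosome 5 had 4.51 ± 0.68 at 882582 to 882921 on the minus strand (SD, n = 5 each). None of the 78 regions passed the test between groups, with 0 at an unadjusted limma p below 0.05. The median sALS minus control log2 difference was 0.265, and 51 of the 78 were higher in sALS. A region lacking a significant peak in any 1 library could not enter this set, so it cannot show whether sites differ. In settings applied to it after seeing the data, the count of 78 was 44 at a −log10 p of at least 5 and 379 at a fold minimum of 2. It was 145 without control 1 and 122 without sALS 1. The 78 regions lay on 18 chromosomes, with 15 on chromosome 1 and 10 on chromosome 19.

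**Figure D1:**
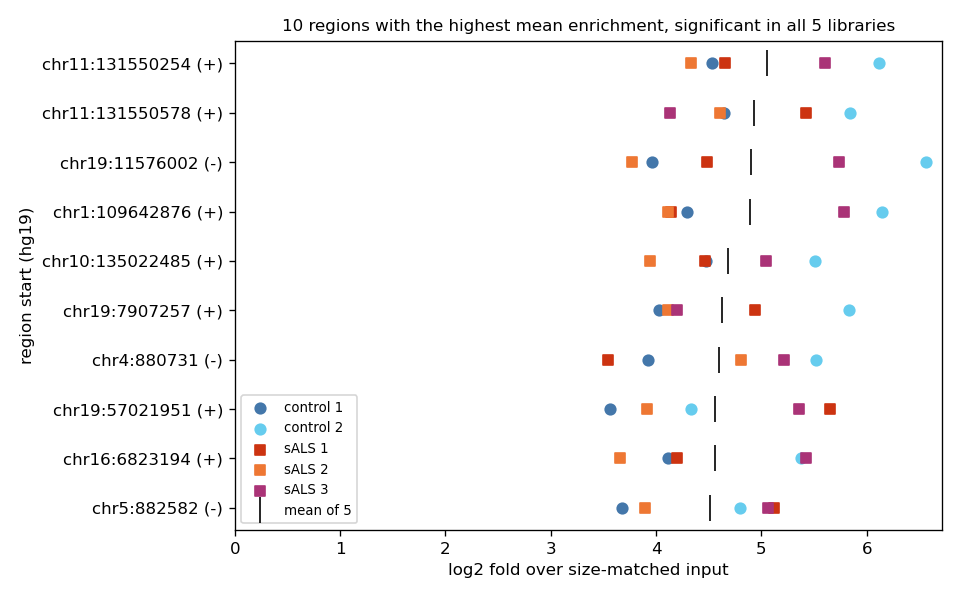
Log2 fold over size-matched input (x axis) at the 10 regions with the highest mean enrichment among those significant in all 5 libraries (y axis, hg19 start and strand). Circles are controls, squares are sALS libraries and the black bar is the mean of 5; the means run from 4.51 to 5.05 and control and sALS libraries are interleaved.

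The −log10 p reached the upper limit of 400 in every library at 2 regions. The region on chromosome 1 at 109642876 to 109642954 did so, with a highest log2 fold of 5.17 in control 1, 6.66 in control 2, 4.50 in sALS 1, 4.66 in sALS 2 and 6.43 in sALS 3. The region on chromosome 11 at 65267831 to 65268273 on the plus strand did so as well, with lower highest folds of 2.58, 3.58, 3.51, 3.37 and 3.43 in the same order. It held 37 peaks at the limit in control 1, 30 in control 2, 6 in sALS 1, 26 in sALS 2 and 23 in sALS 3. Peaks at the limit numbered 51 ± 14.1 in controls (SD, n = 2) and 28 ± 8.54 in sALS (SD, n = 3), with an exact permutation p of 0.1, the smallest that 10 splits allow. That comparison was chosen after the values were seen, and the chromosome 11 region carried the separation: outside it 4 and 31 peaks at the limit remained in controls and 14, 1 and 14 in sALS (exact permutation p of 0.6). The mitochondrial chromosome was below its input in every library, with median log2 folds of −1.04 in control 1, −2.47 in control 2, −2.28 in sALS 1, −2.46 in sALS 2 and −2.41 in sALS 3. None of its 123 to 167 called peaks per library was significant, which allows a share of up to 2.44% in sALS 3, which had the fewest mitochondrial peaks, for counting error only.

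Numbers of significant peaks overlapped between the groups. Control 1 had 2087 and control 2 had 2103, while sALS 1 had 2192, sALS 2 had 1940 and sALS 3 had 2681. The means were 2095 ± 11.3 (SD, n = 2) and 2271 ± 377 (SD, n = 3), with an exact permutation p of 0.8. As a share of called peaks, the control mean was 2.49% ± 0.78 (SD, n = 2) and the sALS mean 3.72% ± 1.73 (SD, n = 3), with an exact permutation p of 0.5. At a fold minimum of 2 the order of the means turned, to 5261 in controls and 3384 in sALS (exact permutation p of 0.2), and for the share to 5.81% and 5.37%. Without sALS 3 the sALS mean lay 29 peaks below the control mean, a difference of −29.

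**Figure D2:**
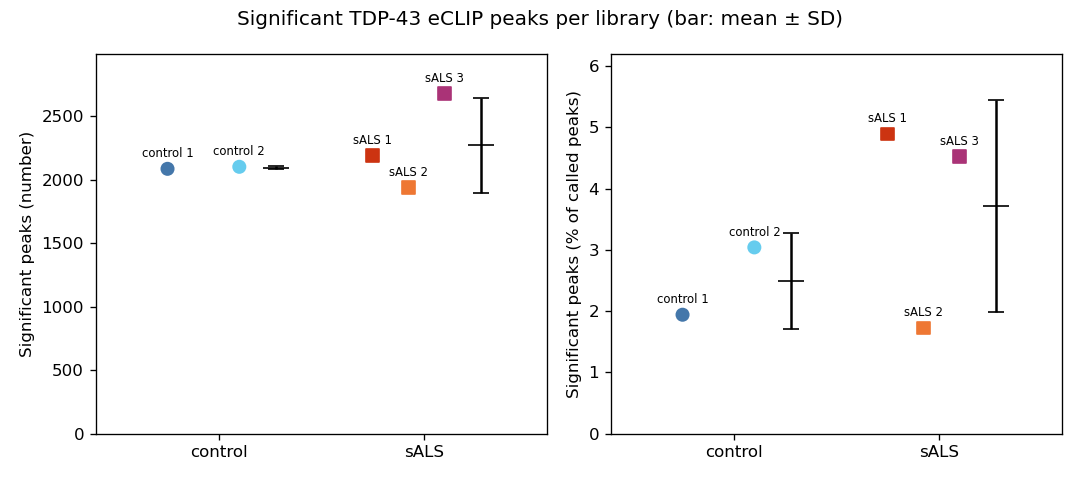
Number of significant peaks (left y axis) and their percentage of called peaks (right y axis) for the 2 control and 3 sALS libraries, with the mean ± SD of each group as a black bar. Numbers run from 1940 to 2681 and percentages from 1.73 to 4.89, with the groups overlapping in both.

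Sharing of significant peaks within and between groups did not differ past the exact test. On average 26.1% of a library's significant peaks were overlapped by a significant peak of another library of its group, and 26.0% by one of the other group, a difference of 0.078 percentage points (exact permutation p of 1). The average within groups joined unlike values, 29.8% over the 3 sALS pairs and 14.9% for the control pair. The pair that shared most was control 2 and sALS 3, at 37.7%, and the pair that shared least was control 1 and control 2. Overlap with any called peak was higher: from 56.0% of the significant peaks of control 2 in sALS 1 to 95.1% of those of sALS 2 in control 1, shared peaks included. The sALS 1 list was the shortest, with 44781 called peaks against 107567 in control 1, so this range need not reflect differences in binding. The difference changed sign at a fold minimum of 2 (−6.19), with a reciprocal overlap of 50% (−0.40), and without sALS 1 (−3.68), sALS 2 (−6.61) or sALS 3 (−0.69). It was 1.25 without control 1 and 6.38 without control 2. Leaving out either control removes the only control pair, so the average within groups is then the 29.8% of the 3 sALS pairs. These 2 values thus compare unlike sets of pairs with the main one. Leaving out an sALS library gives the control pair more weight.

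**Figure D3:**
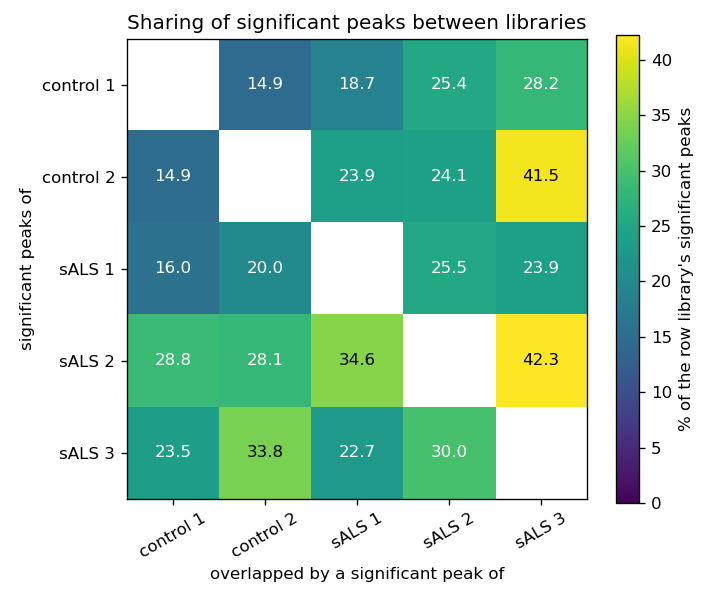
Percentage of the significant peaks of the row library that are overlapped on the same strand by a significant peak of the column library. The control pair has 14.9% in both directions, and the highest value is 42.3%, for sALS 2 peaks in sALS 3.

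Significant peaks in every sALS library and in no control library were found at 60 regions, and the reverse at 23. Among the 60, the region on chromosome 6 at 152650876 to 152651085 on the minus strand had highest log2 folds of 2.09 and 1.82 in controls and 5.34, 4.36 and 4.54 in sALS 1, 2 and 3. On chromosome 19 at 17273160 to 17273261 on the plus strand these were 2.21 and 2.01 in controls and 3.99, 4.28 and 4.49 in sALS. Among the 23, the region on chromosome 9 at 131375659 to 131375744 on the plus strand had 3.95 and 4.43 in controls and 1.38, 2.24 and 2.54 in sALS. The region on chromosome 2 at 135711004 to 135711299 on the plus strand had 4.09 and 3.59 in controls and 0.88, 2.23 and 1.25 in sALS. These 4 were chosen after their values were seen, from those with the widest gap. Many of these sites were called below the minimums in the other group. Among the 60, control 1 had a called peak at all 60 regions and control 2 at 59, with median log2 folds of 2.53 and 2.45 against 3.73 to 3.78 in sALS. Among the 23, sALS 1 had a called peak at 15, sALS 2 at 23 and sALS 3 at 21. With absence taken as no called peak, both counts were 0. Called peaks included weak ones, with a −log10 p of 0 in 39.7% of those of control 1 and 65.8% of those of sALS 2. These counts of 0 therefore do not show that the other group bound the sites. Of the 10 splits of the 5 libraries, others gave up to 78 and 234 regions. Leaving out 1 library moved the 60 to 98 (control 1), 127 (control 2), 196 (sALS 1), 145 (sALS 2) and 203 (sALS 3), and the 23 to 820, 983, 34, 43 and 64; at a fold minimum of 2 the counts were 10 and 46.

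In the 10147 regions called in every library, no region passed the test for a difference between sALS and control. At an unadjusted limma p below 0.05 there were 282 regions, 2.78% of those tested, and without trend and robust fitting there were also 0 calls and 223 such regions. The smallest p belonged to a region lower in sALS on chromosome 17, at 76027595 to 76027791 on the plus strand, with log2 folds of 3.84 ± 0.18 in controls (SD, n = 2) and 0.82 ± 1.56 in sALS (SD, n = 3), a limma adjusted p of 0.809. Next was chromosome 20 at 23356396 to 23356456 on the minus strand, with 4.93 ± 0.96 in controls and 1.96 ± 1.25 in sALS (SD, limma adjusted p of 0.809). In the other direction, chromosome 14 at 72055411 to 72055569 on the plus strand had 1.55 ± 2.32 in controls and 4.03 ± 1.08 in sALS, and chromosome 21 at 47786499 to 47786605 on the plus strand had 1.43 ± 1.18 and 3.88 ± 0.52. The chromosome 6 region at 152650876 was also among the 10 with the smallest p in that direction, with 1.95 ± 0.19 in controls and 4.32 ± 0.51 in sALS and a difference of 2.37 ± 0.80 (SE). The 10 with the smallest p in each direction had differences from 2.12 to 2.47 and from −3.02 to −2.17, and none passed. Over all regions the median difference was 0.16, which was −0.02 without sALS 1, 0.29 without sALS 2 and 0.05 after centring. In the 555 regions with a mean log2 fold of at least 3 it was 0.31, without centring. Without control 1 the region on chromosome 12 at 65641484 to 65641580 on the plus strand was called lower in sALS, by a log2 difference of −5.85 ± 1.17 (SE, limma adjusted p of 0.00545); its values were −0.72 in control 1, 5.37 in control 2 and 0.88, −1.25 and −1.09 in sALS.

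The windows with the highest mean density held significant peaks in all 5 libraries. The 100 kb window on chromosome 16 from 2800001 to 2900000 on the plus strand held 21 and 18 significant peaks in controls and 40, 94 and 36 in sALS 1, 2 and 3. On the minus strand of chromosome 6, the window from 56400001 to 56500000 held 22 and 28 in controls and 22, 89 and 33 in sALS, and its neighbour from 56300001 held 18 and 19 in controls and 27, 71 and 31 in sALS. The window on chromosome 2 from 54800001 to 54900000 on the plus strand held 36 and 14 in controls and 25, 49 and 58 in sALS. Chromosome 1 held 3 of the 10 densest windows, on the plus strand from 39800001, 39700001 and 171500001, with 8 to 23 peaks in controls and 20 to 46 in sALS. The others began at 131300001 on chromosome 9 (+), 114200001 on chromosome 4 (+) and 71700001 on chromosome 11 (−). The 10 windows held 10.3% of the significant peaks of control 1, 6.85% of control 2, 10.7% of sALS 1, 25.4% of sALS 2 and 12.3% of sALS 3.

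**Figure D4:**
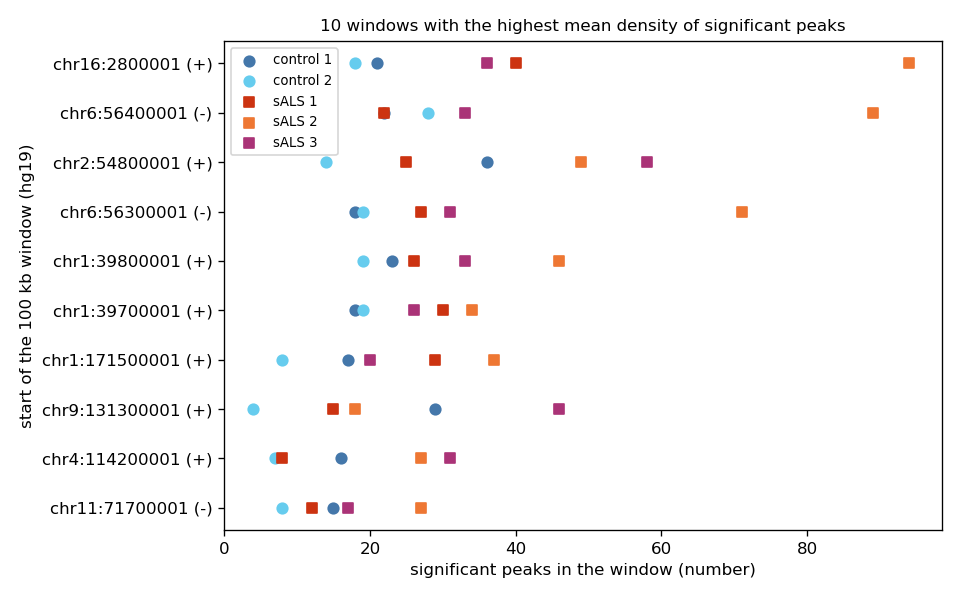
Number of significant peaks per library (x axis) in the 10 stranded 100 kb windows with the highest mean density (y axis, hg19 start and strand); circles are controls and squares are sALS libraries. The highest number is 94, for sALS 2 on chromosome 16.

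Of 530 windows tested, none passed, and 8 had an unadjusted limma p below 0.05, with a smallest adjusted p of 0.996. The smallest p belonged to chromosome 11 from 65200001 to 65300000 on the plus strand, with 0 and 20 significant peaks in controls and 5, 42 and 17 in sALS, a log2 density difference of 2.22 ± 0.91 (SE). It includes the region at 65267831, where control 1 had 37 peaks at the limit of −log10 p but a highest log2 fold of 2.58, below the minimum. Without control 2 this window was called higher in sALS, by 4.89 ± 0.93 (SE, limma adjusted p of 0.000104). Next came chromosome 6 from 56500001 on the minus strand, with 1 and 2 peaks in controls and 9, 20 and 6 in sALS, and chromosome 6 from 31500001 on the minus strand, with 0 and 0 in controls and 6, 3 and 3 in sALS. In the other direction, chromosome 20 from 23300001 on the minus strand had 1 and 18 in controls and 0, 1 and 0 in sALS, and chromosome 7 from 75900001 on the minus strand had 0 and 17 in controls and 0, 0 and 0 in sALS. The 10 windows with the smallest p in each direction had differences of at least 1.28 and from −2.97 to −1.97.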

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

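No alternative brought a difference in the number or share of significant peaks, or in their sharing, past an exact test, which 10 splits cannot do. A fold minimum of 2 reversed the difference in number (−1877 peaks), in share (−0.44 percentage points) and in sharing (−6.19), and a reciprocal overlap of 50% reversed sharing (−0.40); the cause was not tested. At a −log10 p of at least 5 the differences were 26 peaks and 0.539 percentage points. Leaving out each library moved the difference in number between −29 and 341.5. That in share moved from 1.23 to 0.636 (without sALS 1), 0.676 (without control 1) and 2.22 (without sALS 2). That in sharing moved between −6.61 and 6.38, the latter without control 2, where no control pair remains. Regions significant in every sALS and no control library were 35 at a −log10 p of at least 5, 10 at a fold minimum of 2, 0 where no called peak was allowed in controls, and 98 to 203 with 1 library left out. The reverse counts were 5, 46, 0 and 34 to 983; fewer libraries to meet make such sets larger by construction. Regions significant in every library were 44 at the stricter p, 379 at the looser fold, 52 with peaks covering at least 50% of the region and 101 to 145 with 1 library left out, settings applied to this count after seeing the data. Calls in shared regions stayed at 0 in 9 alternatives and were 1 without control 1, a range of 0 to 1 over the libraries left out, with smallest adjusted p from 0.00545 to 0.9999. Calls in windows stayed at 0 in 9 alternatives and were 1 without control 2, a range of 0 to 1, with smallest adjusted p from 0.000104 to 0.997. The median difference over shared regions was −0.0156 without sALS 1, up to 0.292 with other libraries left out, and was above 0 in the other 12 settings able to change its sign, of which the 5 by region strength were chosen after seeing the data; centring gave 0.0454. Other settings for genes, gene lists, genomic features and GU repeats were not run, since they need an annotation or genome of the files' build. No paired analysis was possible because control and sALS libraries come from different donors and their replicate numbers are only names. Read depth is unknown, and 8-fold over 1 input read may have needed from 7 to 50 reads by library, which limits comparisons of significant peaks.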

Other observations

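The comparison of region sets with other splits was planned, with its prediction written after its counts were seen; all other tests here were chosen after the result was seen. Significant peaks lay close together. Of the significant peaks, 45.8% in control 1, 72.5% in control 2, 48.6% in sALS 1, 68.9% in sALS 2 and 65.3% in sALS 3 had another within 1000 bp on the same strand, against means of 3.42% to 6.53% for 1000 random draws of as many called peaks. The group means were 59.1% ± 18.9 (SD, n = 2) and 60.9% ± 10.8 (SD, n = 3), with an exact permutation p of 0.9. The draws took any called peak, of which 5.21% to 65.8% per library had a −log10 p of 0, so they were not matched for signal. Many significant peaks could also lie in 1 short region. The 79 bp region on chromosome 1 from 109642876 held 10, 11, 4, 15 and 13 in the same library order. The excess over the draws therefore does not show that separate sites lay close together. The ratio of the share of significant peaks on chromosome 6 to its share of called peaks was 2.77 in sALS 2 and 1.97 in sALS 1, against 1.42 in control 1, 1.121 in control 2 and 1.40 in sALS 3 (exact permutation p of 0.3 between groups). Chromosome 6 held 13.2% of the 1940 significant peaks of sALS 2. Its adjoining minus-strand windows from 56300001, 56400001 and 56500001 held 71, 89 and 20 of them, against 27, 22 and 9 in sALS 1. The ratio in sALS 2 thus rested largely on 1 stretch and does not describe the whole chromosome. Of the 22 autosomes compared by this ratio, 3 reached the smallest possible exact permutation p of 0.1, where chance gives 2.2 on average; chromosome X was not compared. These had lower ratios in sALS. On chromosome 7 they were 1.09 and 1.13 in controls and 0.968, 0.978 and 0.844 in sALS, and on chromosome 15 they were 0.705 and 0.781 against 0.501, 0.412 and 0.560. On chromosome 20 they were 0.654 in control 1 and 1.48 in control 2 against 0.501, 0.407 and 0.550, so control 2 carried most of that difference. Control 2 had 7 windows with at least 10 significant peaks where no other library had more than 1, sALS 1 had 2 and the other libraries had 0. In 6 of the 7 every other library had a called peak.

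Over the 10147 shared regions sALS 1 lay above the mean of the other libraries by a median log2 of 0.49. A candidate explanation is few reads together with its low ratio of precipitated to input reads, 0.817, since 3 reads over 1 input read would then already give a high fold. Its median excess was 0.82 in the lowest of 5 equal bins of regions by mean −log10 p and 0.190 in the highest, a fall that this explanation would give. Bins made from the −log10 p of the same peaks need not be independent of their folds, so the fall does not decide it. Disease was not excluded: against the mean of the controls the median was −0.107 in sALS 2 and 0.0838 in sALS 3, so they went both ways over all regions. In the highest bin the excess over the other libraries was 0.351 in sALS 3 and −0.0772 in sALS 2 against −0.379 in control 1 and −0.183 in control 2, and the median sALS minus control difference went from 0.103 in the lowest bin to 0.278 in the highest, so disease stays open there.

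The control pair shared the fewest significant peaks of the 10 pairs, 14.9%. The values argue against peaks missed in 1 of the lists as the whole cause. Of the significant peaks, 72.8% in control 1 and 69.5% in control 2 were overlapped by some called peak of the other control. In regions called in all 5 libraries the pair still had the lowest correlation of log2 fold, 0.319 against 0.396 for the next pair. Those regions are not independent. Only 2873 of the 10147 were significant in at least 1 library, so this correlation does not measure sharing of significant peaks. Few reads per peak cannot be told apart from a difference between donors. In the highest bin the control pair had a correlation of 0.0916, again the lowest, against 0.159 to 0.564 for the other pairs. Over all 5 bins 11 of 50 correlations were below 0, none of them in the highest bin. Choosing regions by their mean −log10 p may itself alter such correlations, which was not tested, so that test decides nothing. A difference between the donors was not tested.

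With 10 splits of the 5 libraries no share under 0.05 can be had. The real split gave 60 regions significant in every sALS and no control library, as many as which were found in 4 of the splits, with a highest other of 78. The reverse set held 23, reached by all 10, with a highest other of 234. In shared regions the real split gave 0 calls and the highest other 2, and in windows 0 and 3; any of the 10 splits reaches a count of 0, so these counts decide nothing about chance. At an unadjusted limma p below 0.05 the real split had the fewest regions of the 10, 282 against 372 to 827, but not the fewest windows, 8 against 6 to 67.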
